A study of Mus musculus with 2 samples.

How the data were processed

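The assay was ATAC-seq, in which a transposase inserts sequencing adapters into accessible chromatin, on mouse embryonic stomach at day 14.5. The labels give 1 group with 2 biological replicates, each a pool of male and female embryos, and no other condition. No comparison between groups was therefore possible, and the comparisons below are between the replicates, between gene lists and other genes, and between summits and their flanks.

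The deposited files are peak lists on the mouse build mm10, made by the authors from filtered alignments of each replicate or of both replicates together. Per the file headers and the accompanying notes, they comprise lists ranked or thresholded by the irreproducible discovery rate (IDR, a measure of how reproducibly a peak ranks between 2 sets of reads), pseudoreplicated lists and a replicated list. The deposited signal of each summit is a ratio, an enrichment or fold over the peak caller's background. The deposited significance of each summit is a -log10 p-value. The ranked lists also hold a deposited score for each peak, the -log10 of the global IDR. All 35430 summits of the conservative list were found in the ranked list of both replicates at an IDR of 0.05, which holds 142 further summits on the main chromosomes that the conservative list lacks. The aligner, the peak caller, their versions and any shift of read ends for the transposase are not given in the sources used here. Read counts were not used here, since the files analysed hold none, so the depth of each library is unknown, no interval that needs it is given, and a missing peak is not a measurement of closed chromatin.

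A peak could hold several summits, each listed by the authors as a separate peak with the same start and end, and identical or overlapping peaks were merged into regions. The conservative list was used for both replicates together and the IDR-thresholded list of each replicate for values per replicate. Regions shared between replicates overlapped by at least 1 bp, with chance taken from 100 shuffles within chromosomes in bedtools 2.31.1 and 95% exact binomial intervals, which cover counting error only. Correlations of the -log10 p-value across peaks carry no p-value, since peaks are not independent replicates. The 2 columns of single replicates in the ranked list could not be assigned to replicate numbers.

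Genes were the 21755 protein-coding genes of GENCODE M21 on the 19 autosomes and chromosome X. A promoter was called open when a peak overlapped the window of 1 kb on either side of any annotated transcription start site (TSS). A summit was called distal when it lay more than 1 kb from every protein-coding TSS. Each of 24 gene lists was compared with all other genes by a two-sided Fisher's exact test. Distal summits within 50 kb were compared by the list's median with 10000 random lists matched on the number of neighbouring TSSs, in a two-sided permutation test. Benjamini-Hochberg adjustment was over the 24 lists, with a threshold of 0.05. Members of Hox clusters and of globin clusters are neighbours and are not independent genes, as are some other members of a list, such as Tff1 and Tff2. For 23 consensus motifs, the share of windows of 50 bp on either side of distal summits with a match was divided by the share in flanking windows centred 450 bp away. A motif was called when this ratio exceeded that of every permuted version of its consensus, at most 20 per motif, in both replicates.

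The gene lists, motifs, tests, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover the stomach wall (gut epithelium, forestomach squamous epithelium, mature gastric cells, stomach mesenchyme, smooth muscle, enteric neural crest, endothelium, mesothelium, erythroid cells, leukocytes), other tissues (intestine, pancreas, liver, lung, skeletal muscle, heart, central nervous system, germ cells), housekeeping genes, the cell cycle, the hedgehog response and Hox genes in paralogue groups 1 to 5, 6 to 8 and 9 to 13. The rule named, per list, at most 4 members with the highest pooled signal of a conservative promoter peak, and the unopened members where they numbered at most 5. It also named the 10 strongest distal summits, the 10 genes with most distal summits, the 5 strongest peaks found in 1 replicate and in no list of the other, every Hox gene and every motif. The strength of a peak in each replicate was the highest signal in that replicate's ranked list, and means are given with the SD over n = 2 replicates.

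Chosen after the data were examined were the log2 ratio of signal between replicates, the count of regions in the IDR list of replicate 2 that are not in that of replicate 1 or hold no summit in its ranked list, the log2 ratio by GC content, the gene families, the noncoding classes, the comparison with 10000 random gene lists matched on the CpG content of promoters, in the conservative and in the replicated list, the check for promoter peaks that also lie over a TSS of another gene, and the use of the ratio to permuted consensus sequences, in place of the raw ratio to flanks, when motifs were compared across alternatives. The log2 ratio was tested for the 15 lists with at least 5 measured regions against 10000 random region sets matched on signal and on promoter or distal place. Neither this test nor the count of regions missing from replicate 1 was adjusted for the number of lists. Copies of the strongest distal regions were searched with blastn 2.17.0 in the assembly.

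The alternatives were other peak lists, an IDR of 0.01, other overlap rules, TSS windows of 500 bp and 2 kb, the outermost TSS alone, the top 20000 peaks, distances of 25 and 100 kb, random lists matched also on an open promoter, motif windows of 25 and 100 bp, promoter summits in the motif comparison, and each replicate alone. Added after the data were examined were CpG-matched genes in place of all other genes, the exchange of summits and regions, the strongest summit per region, and 3 variants of the log2 ratio (matching also on GC content, promoter regions alone, distal regions alone). Chromosome Y and unplaced contigs were left out of the gene comparisons.

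The methods were tested on simulated data. All 80 planted open-promoter lists and all 40 planted distal lists were recovered. Of lists without a planted difference, 1 of 400 was called for promoters and 21 of 440 for distal summits, 20 of them the hedgehog response list, which shares 5 members with the planted mesenchyme list. Simulated promoters opened independently of CpG content and of neighbouring genes, and planted promoter lists were wholly open or wholly closed. These rates therefore need not hold for the deposited peaks. All 15 planted motifs were recovered in a single peak set, and 6 of 100 others were called. All 5 planted shifts of the log2 ratio were recovered, and 2 of 70 other lists fell outside their range. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, together with samtools 1.23.1.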

Results

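The data were peak lists from ATAC-seq of mouse stomach at embryonic day 14.5, from 2 biological replicates of 1 group. At this stage the stomach wall holds an epithelium of endodermal origin, mesenchyme, developing smooth muscle, nerves, vessels and an outer mesothelium. The conservative list holds peaks of the pooled replicates that ranked reproducibly between them, which is not the same as a peak in each replicate's own list. Of 92 named-list genes open in it, 9 were open in the IDR list of neither replicate (Bhlha15, Erbb3, Erg, Hba-a1, Hoxa4, Kdr, Krt8, Pdx1 and Satb2). It held 35430 summits in 14611 regions that covered 13.66 Mb, with a median region of 922 bp. The deposited files give no total count per library, so the depth of neither replicate is known.

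Promoters of dividing cells and of general cell functions were open almost without exception, and promoters of many other tissues were mostly without a peak. Of 21755 protein-coding genes, 11134 (51.2%) had an open promoter. All 12 cell cycle genes had one, against 51.2% of all genes (Fisher's exact test, adjusted p = 0.00606). Ccna2, a cyclin of S phase and mitosis, had a signal of 17.2 ± 0.705 (SD, n = 2), and Ccnb1, the mitotic cyclin B1, one of 14.8 ± 1.77. Mcm5, part of the replicative helicase, reached 14.2 ± 0.982 and Pcna, the sliding clamp of DNA polymerase, 14.5 ± 0.261. Of 14 housekeeping genes 13 were open (adjusted p = 0.00918 by the exact test), with the ribosomal protein gene Rplp0 at 14.99 ± 0.353, the elongation factor Eef1a1 at 14.2 ± 0.159, the glycolytic enzyme Pgk1 at 13.74 ± 3.67 and the transferrin receptor Tfrc at 13.6 ± 1.47. The polyubiquitin gene Ubc was the member without a conservative peak. With the outermost TSS of each gene alone, the housekeeping share was 78.6% and no longer passed (adjusted p = 0.0555, exact test). Neither list passed against genes matched on promoter CpG content, among which 9.81 of 12 (middle 95% 7 to 12, permutation test, adjusted p = 0.265) and 11.7 of 14 (9 to 14, adjusted p = 0.781) were open. These ranges reach every gene of the list, so even a wholly open list could not have passed. The comparison therefore does not decide whether CpG content accounts for these open promoters.

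**Figure D1:**
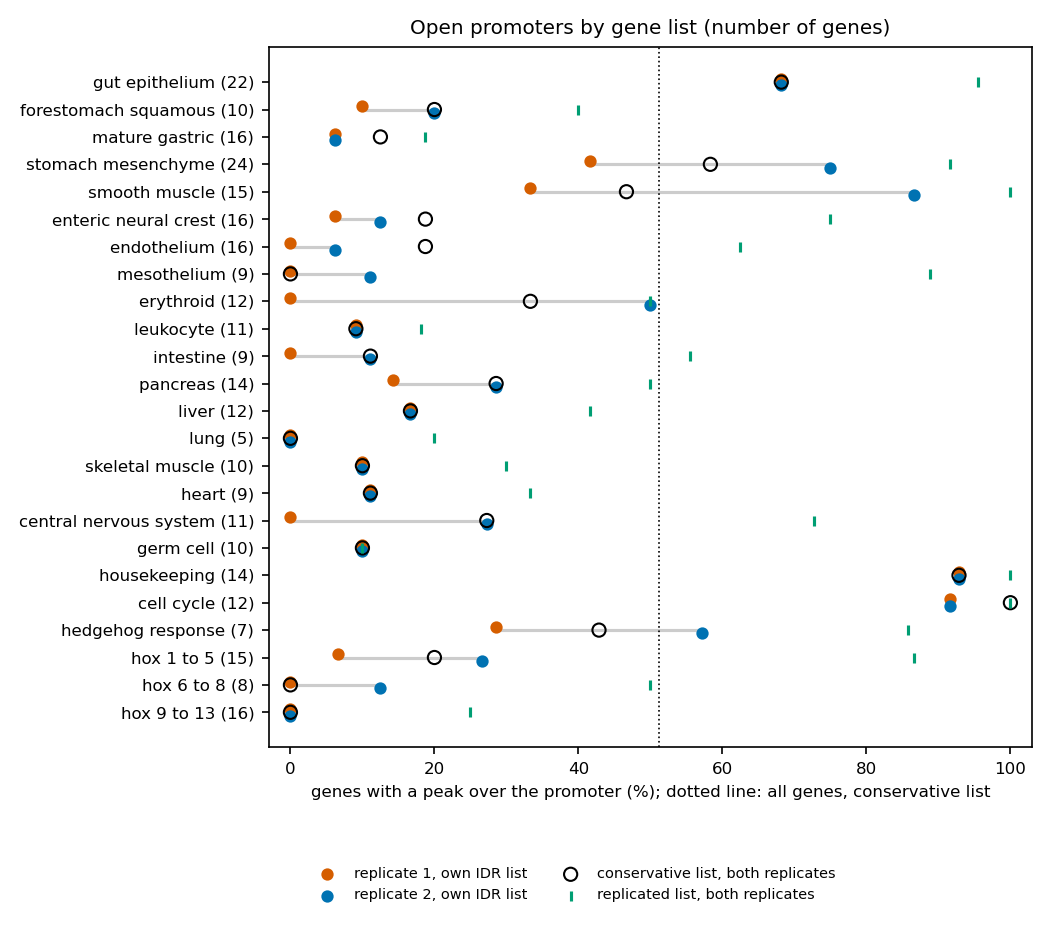
Percent of the genes of each list with an open promoter, in the conservative list (open circles), in each replicate (filled circles) and in the replicated list (ticks), with a dotted line at the share of all genes, 51.2%. In the conservative list all 12 cell cycle genes were open, and none of the 16 genes of Hox groups 9 to 13 was.

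Gut epithelial genes were open in 15 of 22 cases (68.2%), the same number but not all the same genes in each replicate's own list, and this did not pass the test (adjusted p = 0.165, exact test). The highest signals were at Klf5, a regulator of epithelial proliferation (11.8 ± 1.28, SD, n = 2; gene at chromosome 14, 99298691 to 99315036), Foxa3, a forkhead factor of the endoderm (9.47 ± 2.56; chromosome 7, 19013284 to 19023538), the epithelial cadherin gene Cdh1 (9.75 ± 1.95; chromosome 8, 106603351 to 106670246) and Sox2, a factor of foregut identity (7.73 ± 0.714; chromosome 3, 34650405 to 34652461). The peak at Foxa3 also lay over a TSS of Sympk. In the authors' replicated list, which is less strict and opened 14290 genes (65.7%), 21 of the 22 epithelial genes were open (adjusted p = 0.00973, exact test), which did not pass against CpG-matched genes (18.1 open, adjusted p = 0.302, permutation test). With replicate 1 alone, where Hnf4a, Cldn4 and Krt19 were open and Gata4, Grhl2 and Krt8 were not, the list also passed (adjusted p = 0.0318, exact test).

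Among mesenchymal genes 14 of 24 (58.3%) had an open promoter, and among smooth muscle genes 7 of 15 (46.7%). Neither share passed the test (adjusted p = 0.593 and 0.8, exact tests). The mesenchymal share fell below that of other genes with the outermost TSS alone (37.5%) and against CpG-matched genes (18.1 open, adjusted p = 0.168, permutation test), and was 41.7% in replicate 1 and 75% in replicate 2. Pbx1, a homeodomain cofactor, had the highest mesenchymal signal at 14.4 ± 0.121 (SD, n = 2; chromosome 1, 168119364 to 168432270). In order of pooled signal it was followed by Isl1, a LIM homeodomain factor, at 10.1 ± 0.301, the hedgehog effector Gli3 at 9.21 ± 1.11 and the homeobox gene Six2 at 9.61 ± 0.138. In smooth muscle Srf, the factor that binds CArG boxes, had 10.4 ± 0.173 and its coactivator Myocd 6.38 ± 1.88, beside the contractile genes Tpm1 at 10.1 ± 0.930 and Smtn at 7.70 ± 1.24. The replicated list opened 22 of the 24 mesenchymal genes (adjusted p = 0.0147) and all 15 smooth muscle genes (adjusted p = 0.00973) by the exact test. Against CpG-matched genes in that list, smooth muscle passed (9.01 open, middle 95% 6 to 12, adjusted p = 0.0032, permutation test) and mesenchyme did not (21.8 open, adjusted p = 1). The mesenchymal range, 19 to 24, reaches all 24 genes, so even a wholly open list could not have passed. With replicate 2 alone 13 smooth muscle genes were open (86.7%, adjusted p = 0.0209, exact test), and with replicate 1 alone 5. Of 7 hedgehog response genes, Foxf1 (5.71 ± 0.943), Gli1 (5.33 ± 0.0327) and Ptch1 (4.57 ± 0.520) were open, and Ptch2, Hhip, Foxl1 and Bmp4 were not (adjusted p = 0.752, exact test; 2 open in replicate 1 and 4 in replicate 2; 14.3% with the outermost TSS alone). The replicated list opened 6 of the 7 (85.7% against 65.7%), which turned the direction (adjusted p = 0.549, exact test); 5 of these 7 genes are also in the mesenchymal list.

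Genes of mature gastric cells were open in 2 of 16 cases (12.5%), below other genes (adjusted p = 0.00918, exact test). These were Cldn18, a tight junction gene (7.86 ± 0.946, SD, n = 2), and Bhlha15, a factor of secretory cells (4.92 ± 0.368). The replicated list had 3 of 16 open, still below other genes (adjusted p = 0.00388, exact test). In each replicate's own list 1 was open. CpG-matched genes had 1.74 open in the conservative list, so the count of 2 did not differ from theirs (adjusted p = 1, permutation test). Forestomach squamous genes were open in 2 of 10 cases, Pax9 (8.69 ± 0.199) and Sfn (4.69 ± 0.145), with 1 open in the list of replicate 1 and 2 in that of replicate 2, which did not pass the exact test (adjusted p = 0.0844), but with the outermost TSS alone 10% were open and the list was below other genes (adjusted p = 0.0453).

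The enteric neural crest, endothelium, mesothelium and leukocyte lists were mostly without conservative peaks. Enteric neural crest had 3 of 16 open (1 in the list of replicate 1 and 2 in that of replicate 2; adjusted p = 0.0241, exact test): the neuronal gene Elavl4 (7.16 ± 1.43, SD, n = 2), the receptor Ret (5.51 ± 0.325) and Erbb3 (4.44 ± 0.359). Endothelium also had 3 of 16 (0 in the list of replicate 1 and 1 in that of replicate 2; adjusted p = 0.0241, exact test): the VEGF receptor Kdr (5.99 ± 0.960), Egfl7 (4.79 ± 0.753) and Erg, at 5.86 in the ranked list of replicate 2 and without a peak in that of replicate 1. The peak at Egfl7 also lay over the TSS of another annotated gene. No mesothelial gene of 9 was open (0 in replicate 1 and 1 in replicate 2; adjusted p = 0.00918, exact test), and of 11 leukocyte genes Runx1 alone was (8.37 ± 0.0476; adjusted p = 0.0183, exact test). In the replicated list 12 of the 16 enteric genes (75%), 10 of the 16 endothelial genes (62.5%) and 8 of the 9 mesothelial genes (88.9%) were open. None of these lists passed the exact test there, with endothelium still slightly under the 65.7% of other genes (adjusted p = 0.796). The leukocyte list, with 2 of 11, remained below (adjusted p = 0.00973, exact test), whereas with replicate 1 alone it did not pass (adjusted p = 0.0542, exact test), nor did its count of 1 against CpG-matched genes (1.65 open, adjusted p = 1, permutation test).

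Erythroid genes were open in 4 of 12 cases (33.3%, adjusted p = 0.294, exact test), and the replicates differed at them. Nfe2, an erythroid factor, had a signal of 5.56 in replicate 1 and 9.76 in replicate 2. The erythropoietin receptor gene Epor had 5.25 and 8.45. Klf1, a regulator of globin genes, had 8.10 in replicate 2 and Hba-a1, an alpha globin gene, 4.93, and neither had a peak in the ranked list of replicate 1. In the IDR-thresholded lists 6 of the 12 genes were open in replicate 2 and 0 in replicate 1, where the list was below other genes (adjusted p = 0.00972, exact test). Against CpG-matched genes the direction turned, with 4 open against 1.27 (middle 95% 0 to 3, adjusted p = 0.0517, permutation test), and 6 against 2.62 in the replicated list (1 to 5, adjusted p = 0.0744).

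Genes of neighbouring and unrelated tissues had few open promoters. Lung genes had 0 of 5 (Nkx2-1, Sftpc, Sftpb, Sftpa1 and Scgb1a1; adjusted p = 0.0416), intestinal genes 1 of 9 (Satb2, 5.05 ± 0.932, SD, n = 2; adjusted p = 0.0316) and liver genes 2 of 12 (Apoh, 10.1 ± 0.165, and Prox1, 5.45 ± 0.981; adjusted p = 0.0316), all by the exact test. Skeletal muscle had 1 of 10 (Actn3, 10.9 ± 2.43; adjusted p = 0.0241), heart 1 of 9 (Tbx20, 7.40 ± 0.332; adjusted p = 0.0316) and germ cells 1 of 10 (Dazl, 10.4 ± 0.956; adjusted p = 0.0241), again by the exact test. The peaks at Apoh and Actn3 also lay over TSSs of Prkca and Zdhhc24. In the replicated list the germ cell list remained below other genes at 1 of 10 (adjusted p = 0.00545, exact test), and the lung (20%), intestine (55.6%), liver (41.7%), skeletal muscle (30%) and heart (33.3%) lists did not pass singly. Pooled, these 5 lists remained below other genes there, with 17 of 45 genes open (37.8% against 65.7%, p = 0.000201, Fisher's exact test). They were pooled once known to be below other genes in the conservative list, which favours this outcome. With replicate 1 alone, the lung, liver, skeletal muscle, heart and germ cell lists did not pass, and with the outermost TSS alone the lung, liver, skeletal muscle and heart lists did not. The liver list was also lost with a TSS window of 2 kb (25%, adjusted p = 0.116, exact test). Against CpG-matched genes the lung, intestine, liver, skeletal muscle and heart lists did not pass in the conservative list, and the germ cell list did (adjusted p = 0.024, permutation test).

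Pancreatic genes had 4 of 14 open (2 in replicate 1 and 4 in replicate 2), which did not pass the exact test (adjusted p = 0.148). These were Nkx6-1 (11.5 ± 0.506, SD, n = 2), Arx (9.33 ± 0.788), Rfx6 (6.28 ± 0.854) and Pdx1 (4.99 ± 0.560), all transcription factors of pancreatic or endocrine cells. Central nervous system genes had 3 of 11 open (adjusted p = 0.165, exact test): Lhx2 (8.51 ± 2.79), Dlx1 (6.94 ± 0.661) and Foxg1 (5.13 ± 1.21), whose peak also lay over the TSS of another annotated gene. With replicate 1 alone, 0 of these 11 genes were open and the list was below other genes (adjusted p = 0.0112, exact test), as it was with the outermost TSS alone at 9.09% (adjusted p = 0.0328) and against CpG-matched genes (7.88 open, adjusted p = 0.00891, permutation test). The replicated list turned the direction, with 8 of 11 open (72.7% against 65.7%, adjusted p = 0.792, exact test), and there the list did not pass against CpG-matched genes either (9.55 open, adjusted p = 0.473, permutation test).

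Hox genes, which set position along the body axis, had conservative promoter peaks at anterior members alone. In paralogue groups 1 to 5, 3 of 15 genes were open: Hoxa1 (6.33 ± 0.692, SD, n = 2) and Hoxa4 (4.57 ± 0.149) on chromosome 6 and Hoxb4 (5.92 ± 0.617) on chromosome 11. None of the 8 genes of groups 6 to 8 and none of the 16 genes of groups 9 to 13 had a conservative peak. In the lists of replicate 1 and replicate 2, 1 and 4 genes of groups 1 to 5 and 0 and 1 of groups 6 to 8 were open. All 3 lists were below other genes by the exact test, with adjusted p = 0.0316, 0.0129 and 0.000249. In the replicated list 13 of 15 anterior genes (86.7%) were open, which turned the direction (adjusted p = 0.181, exact test), and 4 of 8 in groups 6 to 8 (adjusted p = 0.550), whereas groups 9 to 13 remained below with 4 of 16 (adjusted p = 0.00849). Against CpG-matched genes in the replicated list, groups 6 to 8 (7.25 open, adjusted p = 0.0048) and 9 to 13 (14.8 open, adjusted p = 0.0024) were below by the permutation test. With replicate 2 alone, or with the outermost TSS alone, groups 1 to 5 did not pass (adjusted p = 0.0843 and 0.0603, exact tests).

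The replicated list opened Hoxa2, Hoxa3 and Hoxa5, Hoxb1, Hoxb2 and Hoxb5, Hoxc4 and Hoxc5, and Hoxd1 and Hoxd3 in addition. Of groups 6 to 8 it opened Hoxa7, Hoxb6, Hoxb7 and Hoxd8, and of groups 9 to 13 Hoxa13, Hoxc10, Hoxc13 and Hoxd13. Without a peak in either list were, in the A cluster, Hoxa6, Hoxa9, Hoxa10 and Hoxa11, and in the B cluster on chromosome 11, Hoxb3, Hoxb8, Hoxb9 and Hoxb13. In the C cluster on chromosome 15 these were Hoxc6, Hoxc8, Hoxc9, Hoxc11 and Hoxc12, and in the D cluster on chromosome 2, Hoxd4, Hoxd9, Hoxd10, Hoxd11 and Hoxd12.

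**Figure D2:**
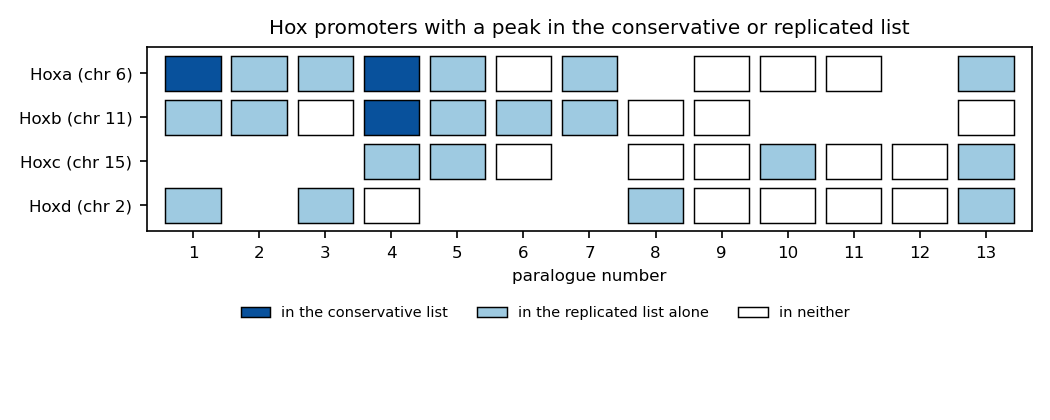
Hox genes by cluster and paralogue group, with each gene marked by the list in which its promoter was open. The conservative list opened Hoxa1, Hoxa4 and Hoxb4, and the 16 genes of groups 9 to 13 were without a conservative peak.

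Gut epithelial genes also had more distal peaks than other genes. Their median was 2 distal summits within 50 kb, against 0 in random lists, and 16 of the 22 genes had at least 1 (adjusted p = 0.0048, permutation test, from p = 0.0002, the smallest that these permutations can give). Gata4, an endodermal zinc finger factor, and Krt8, a keratin of simple epithelia, had 7 each (6.5 ± 0.707 and 3 ± 2.83 in the replicates, SD, n = 2; 1 at Krt8 in replicate 1) and were named after their values were seen. The mean was 2.27 summits per gene, against 0.592 in random lists, and 1.59 in each replicate's own list, where the medians were 1 in replicate 1 and 1.5 in replicate 2. Krt18, a neighbour of Krt8 on chromosome 15, had 5 summits, so the same summit may count more than once in this list. Counted as regions in place of summits, the median was 1 and the list did not pass (adjusted p = 0.0768, permutation test).

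No other list passed in the conservative list by its median. By the mean, genes of mature gastric cells had 1.94 distal summits against 0.643 in random lists (adjusted p = 0.0464, permutation test; by the median 0.24; 0.875 and 1.06 summits in the lists of replicates 1 and 2), and Hox groups 9 to 13 had 0 against 0.896 (adjusted p = 0.0336; by the median 1; 0 and 0.25 summits). With replicate 2 alone, stomach mesenchyme (adjusted p = 0.0336), erythroid genes (0.0304) and Hox groups 1 to 5 (0.0048) passed the permutation test too. Erythroid genes had a mean of 2.33 distal summits in replicate 2 and 0.333 in replicate 1, mesenchymal genes 1.67 and 0.542, and Hox groups 1 to 5 2.53 and 0. Neighbouring globin genes and neighbouring Hox genes can share distal summits, so the same summit may count more than once in these lists. This holds too for the mature gastric genes Tff1 and Tff2, neighbours on chromosome 17 with 4 summits each. Random lists draw scattered genes, so their ranges may be too narrow for such lists. In the replicated list 6 lists passed: gut epithelium, mature gastric cells, stomach mesenchyme, smooth muscle and Hox groups 1 to 5 and 6 to 8.

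The genes with most distal summits were not members of these lists. Fcgr3, an Fc receptor gene (chromosome 1, 171051174 to 171064935), had 21, and 17 ± 9.90 in the replicates (SD, n = 2). Eapp had 19 (17.5 ± 4.95), the germ cell gene Tex14 17 (16.5 ± 3.54), and Igf2r, the receptor that clears IGF2, 15 (5.0 ± 4.24). BC107364 had 14 (15 ± 2.83), Cfap126, Klrb1c and Mreg 13 each (12 ± 7.07, 6 ± 5.66 and 11 ± 2.83), and the cyclin gene Ccnd3 and Cyb5d1 11 each (9 ± 2.83 and 4.5 ± 0.707). Among all genes the median was 0, 73.9% had none and the mean was 0.646.

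The strongest distal summits lay outside coding sequence, as did most distal summits, with 286 of all 7992 in coding exons. The highest, on chromosome X from 143482936 to 143483180, was intergenic, 35531 bp from the TSS of Pak3, with a signal of 54.0 ± 0.942 (SD, n = 2). The next, on chromosome 2 from 69355469 to 69355735, was intergenic, 12987 bp from Abcb11, at 50.2 ± 5.48. An intron of the noncoding gene AC115970.1 on chromosome 10, from 96077546 to 96077951 and nearest to Gm5426, had 43.1 ± 0.907. Intergenic regions on chromosome 5 from 60042765 to 60043136 (nearest G6pd2) and on chromosome 2 from 3964423 to 3964690 (nearest Frmd4a) had 41.2 ± 1.93 and 37.9 ± 0.628. An exon of Gm11407 on chromosome 4, from 80002698 to 80003057 and nearest to Tyrp1, had 29.6 ± 0.00484. The regions on chromosomes 10, 5 and 4 have a copy in mitochondrial DNA.

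The remaining strongest distal summits were an intergenic pair in a single region on chromosome 12, from 97061368 to 97061856 and 1181917 bp from Galc (29.0 ± 0.426, SD, n = 2), an intron of Gm26561 on chromosome 17, from 70963584 to 70963961 and nearest to Myl12b (25.5 ± 2.26), and an intergenic region on chromosome 16, from 17222207 to 17222566 and nearest to Hic2 (24.96 ± 2.17).

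Most peaks lay at promoters. Of 35425 conservative summits on the autosomes and chromosome X, 27433 (77.4%, 95% exact binomial interval 77 to 77.9) lay within 1 kb of a protein-coding TSS, against 2.68% after shuffling, a 28.9-fold difference. The share was 80.4% in replicate 1 and 73.8% in replicate 2 (mean 77.1% ± 4.68, SD, n = 2). Introns held 10.1% ± 1.98, intergenic sequence 10.2% ± 2.20, coding exons 0.639% ± 0.25 and other exons 1.99% ± 0.245. The promoter share was 42.8% in the replicated list.

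Replicate 2 had more and longer accessible regions. Its own list held 16313 regions over 14.24 Mb, against 11232 regions over 8.03 Mb in replicate 1 (mean 13772.5 ± 3593, SD, n = 2), a ratio of 1.45. The median deposited signal was 5.53 in replicate 2 and 6.50 in replicate 1. Of the regions of replicate 1, 9971 (88.8%, 95% exact binomial interval 88.2 to 89.3) overlapped a region of replicate 2, against 1.08% of shuffled regions. Of the regions of replicate 2, 9769 (59.9%, interval 59.1 to 60.6) overlapped a region of replicate 1, against 0.731%. Regions that were not shared were weaker, with median signals of 6.65 against 9.16 in replicate 1 and 6.67 against 10.5 in replicate 2. Across 87950 peaks of the ranked list, the -log10 p-values of the replicates had a Spearman correlation of 0.597 and a Pearson correlation of 0.869, across peaks, which are not independent replicates.

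Some regions appeared in a single replicate. In replicate 1, 184 summits overlapped no peak of any list of replicate 2. The strongest were intergenic near Arl2bp (chromosome 8, 94660400 to 94660872, signal 12.8), in an intron of Dcaf17 (10.9), in a noncoding exon of Syt11 (9.96), and intergenic near Pcdh9 (9.46) and Thoc3 (9.04). In replicate 2 there were 3240 such summits. The strongest lay at the promoter of the zinc finger gene Zfp932 (chromosome 5, 109996099 to 109996827, signal 17.5), in an intron of 2610206C17Rik near Zfand6 (16.8), in an intron of Naaladl2 (14.97), between genes near Abca1 (13.8) and at the promoter of Zfp449 (chromosome X, 56346098 to 56347123, 13.6).

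Signal at gut epithelial genes was tilted towards replicate 1, while most other regions were tilted towards replicate 2. Across 15280 regions measured in both replicates, the median log2 ratio of replicate 2 to replicate 1 was 0.20. In the 46 regions of gut epithelial genes it was -0.19 (quartiles -0.46 to 0.14), with 15 regions higher in replicate 2, and matched random sets gave 0.04 to 0.36 in their middle 95%. The 12 regions of mature gastric genes had -0.23 (percentile 1.6), with matched sets at -0.19 to 0.48, and this did not pass among distal regions alone. The ranges are not adjusted for the 15 lists tested. Matched sets draw scattered regions, so the ranges may be too narrow for lists with several regions per gene. The other 13 lists tested lay within their range, with smooth muscle at 0.16, stomach mesenchyme at 0.05, housekeeping at 0.06, cell cycle at 0.20 and erythroid genes at 0.13 over 5 regions. Stomach mesenchyme fell below its range when the sets were matched also on GC content, and housekeeping when promoter regions alone were used.

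**Figure D3:**
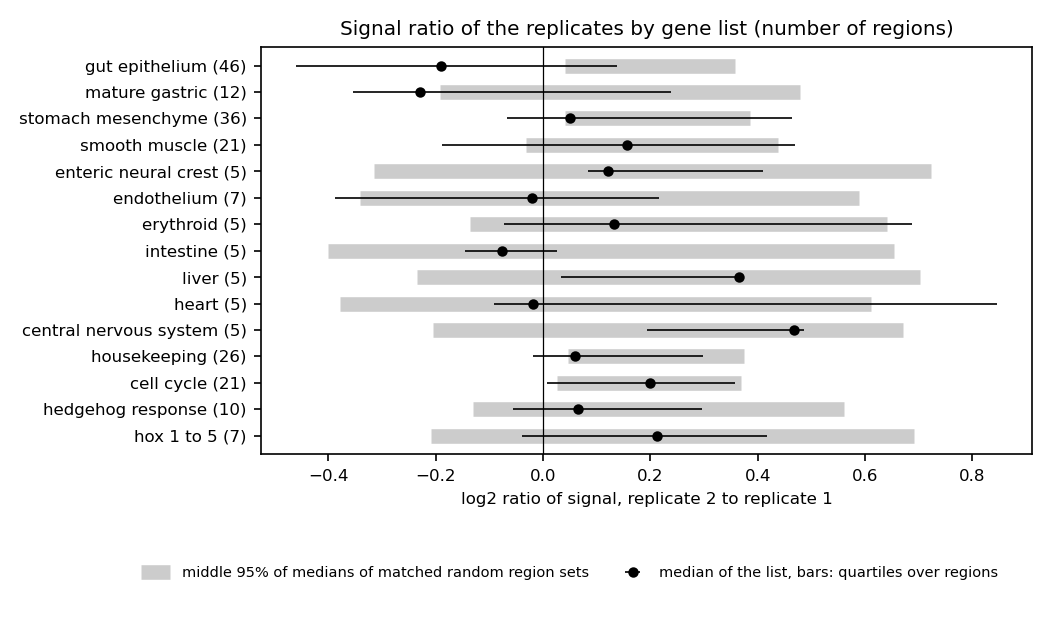
Median log2 ratio of deposited signal, replicate 2 to replicate 1, of the regions of each gene list, with bars for the quartiles over regions, beside the middle 95% of matched random region sets in grey. Gut epithelial genes sit at -0.19 and mature gastric genes at -0.23, both below their ranges.

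Most erythroid regions of replicate 2 were not in the IDR list of replicate 1. Of the 19 regions of erythroid genes in the IDR list of replicate 2, 17 (89.5%) were not in that of replicate 1, against 10.3 in sets matched on the signal in replicate 2 (middle 95% 6 to 14). In 15 of the 19 the ranked list of replicate 1 held no summit, against 3.59 (1 to 7), so the erythroid log2 ratio rests on few regions. Globin genes are neighbours and can share regions. Hbb-bt, Hbb-bs and Hbb-y on chromosome 7 had 4, 5 and 5 distal summits in replicate 2 and 0 each in replicate 1. The matched sets draw scattered regions, so these erythroid ranges may be too narrow for linked ones. Of 33 gut epithelial regions 10 were not in the IDR list of replicate 1, against 20.3 (15 to 25), and 2 held no summit, against 6.91 (3 to 11). Of 10 mature gastric regions 3 were not in that list, against 6.68 (4 to 9). Stomach mesenchyme, with 23 of 41 regions outside the IDR list of replicate 1, of which 6 held no summit in its ranked list, and smooth muscle, with 16 of 27 and 8, lay within their ranges. So did the other 13 of the 18 lists tested in the count outside the IDR list.

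Distal summits held motifs of architectural and lineage factors. Of 23 motifs, 7 were called: CTCF, the insulator protein (6.17 times as frequent at summits as in flanks; replicates 6.71 ± 0.495, SD, n = 2), AP1 (2.52; 2.85 ± 0.379), KLF and SP factors (2.59; 2.804 ± 0.294), NFY (2.06; 2.07 ± 0.291), ETS (2.0; 2.03 ± 0.352), GATA (0.882; 1.19 ± 0.135) and FOX (0.818; 0.937 ± 0.215). GATA and FOX matches, which are rich in A and T, were rarer at summits than in flanks in the conservative list, with ratios 1.87 and 2.11 times those of the permuted versions. GATA had ratios of 1.28 and 1.09 in replicates 1 and 2, and FOX of 1.09 and 0.785, so this direction held in neither replicate for GATA and in replicate 2 alone for FOX. The KLF and SP consensus was set against only 5 permuted versions (highest ratio 2.42) and CTCF against 14, while the other called motifs had 20. The KLF and SP call is therefore easier to reach by chance. The CTCF call was lost with windows of 100 bp, and that of KLF and SP factors with windows of 25 bp. At promoter summits CTCF, AP1 and GATA were not called. The CArG box and NRF1 gained a call at promoter summits, the CArG box and HNF4 with windows of 25 bp, and TEAD, HOX/PBX and HNF1 with windows of 100 bp.

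**Figure D4:**
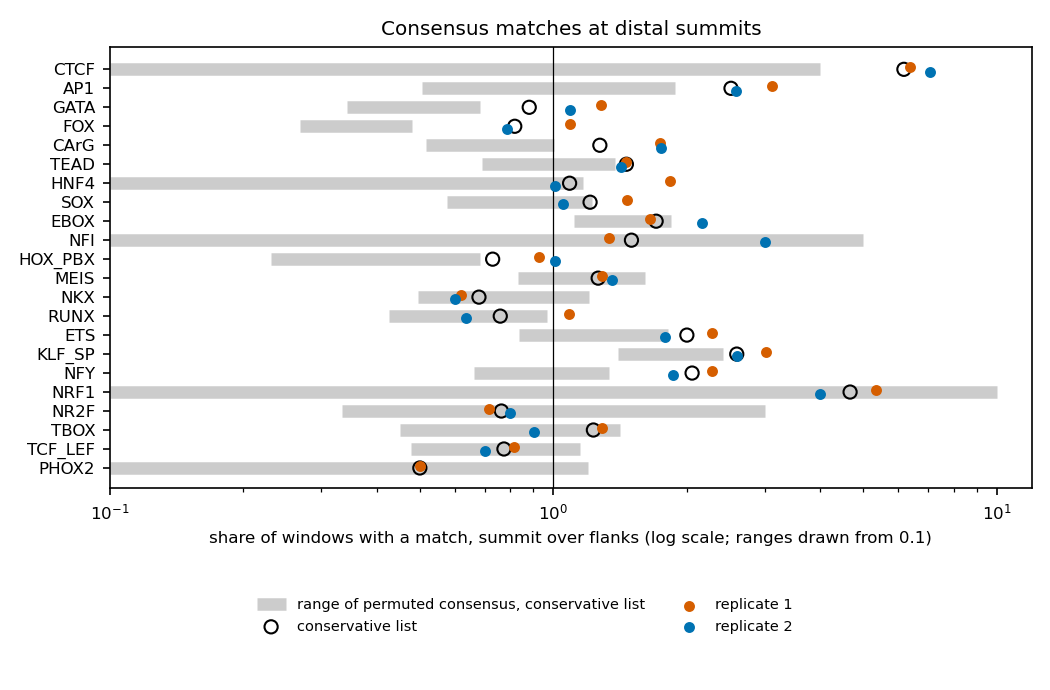
Ratio of the share of distal summit windows with a motif match to the share of flanking windows, for the 23 motifs without HNF1, on a log axis, in the conservative list (open circles) and in each replicate (filled circles), with grey bars for the range of permuted consensus sequences. CTCF has the highest ratio of the 7 called motifs, 6.17.

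The other 16 motifs were not called. Their ratios of summits to flanks were 4.67 for NRF1, 1.71 for the E-box, 1.5 for NFI, 1.46 for TEAD, 1.27 for the CArG box, 1.26 for MEIS, 1.23 for T-box, 1.21 for SOX and 1.09 for HNF4. They were below 1 for TCF/LEF (0.774), NR2F (0.764), RUNX (0.759), HOX/PBX (0.730), NKX (0.680) and PHOX2 (0.5). HNF1 matched 0.0626% of summit windows and 0.00626% of flanks, a ratio of 10 from very few windows. With replicate 2 alone the CArG box, the E-box, NFI, HOX/PBX and HNF1 were called in addition, and with replicate 1 alone HNF4 was, whose ratio was 1.83 in replicate 1 and 1.01 in replicate 2. TEAD, HNF4, the E-box, HOX/PBX, NRF1 and HNF1 were called in addition in the replicated list.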

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

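All of the counts in this part were made after the data were examined, and no explanation was tested for them. In the ranked list of both replicates, 68 summits at an IDR of 0.05 lay on 13 unplaced or unlocalized contigs, which the comparisons left out, and a count of 0 would allow up to 3. Their median signal was 3.29 and the highest 29.6, against a median of 5.25 for all summits at that threshold, and a single contig held 28 of them. The IDR list of the pooled reads held 10859 summits that the conservative list lacks, of which 68.4% were distal, with a median signal of 4.41. Chromosome Y, which was also left out of the gene comparisons, held 5 conservative summits in 5 regions, with a highest signal of 12.9. The pools comprised male and female embryos per the labels.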

How the results depend on the processing

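Chosen only after the results were seen were CpG-matched genes, the exchange of summits and regions, the strongest summit per region and the variants of the log2 ratio; the other alternatives were planned, and for every change below the cause was not tested. The ratio of regions, replicate 2 to replicate 1, was 1.66 with pseudoreplicated lists, 1.89 at an IDR of 0.01 and 1.73 for summits. The share of replicate 1 regions found in replicate 2 was 78.5% with a reciprocal overlap of 50%, 79.4% with pseudoreplicated lists, 98.6% against the ranked list, 76.5% with equal numbers of top regions and 92.1% for summits. The share of replicate 2 regions found in replicate 1 was 54.0%, 45.7%, 87.1%, 74.9% and 65.1% under the same alternatives. The Spearman correlation was 0.709 with the strongest summit per region, and the Pearson correlation 0.706 on the log10 scale. The promoter share was 67.5% with a window of 500 bp, 67.3% in the pooled IDR list, 42.8% in the replicated list, 87.4% at an IDR of 0.01, and 73.8 to 80.4% with a replicate left out. In the replicated list 5 gene lists lay above other genes in open promoters and 4 below, and enteric neural crest (75%), mesothelium (88.9%) and Hox groups 1 to 5 (86.7%) changed side, as did smooth muscle, central nervous system and hedgehog response, which had no call; with the outermost TSS 1 list lay above. Against CpG-matched genes 0 lists lay above and 8 below, and mature gastric cells (12.5%, against 1.74 of 16 genes expected) changed side, as did stomach mesenchyme, smooth muscle and erythroid genes, which had no call. By distal summits 6 lists passed in the replicated list, 1 to 4 with a replicate left out and 0 with regions. The number of motifs called was 13 in the replicated list and 8 to 12 with a replicate left out, where a call needed 1 peak set in place of both replicates. By the log2 ratio 1 list lay off its range among distal regions. Of 192 comparisons of a list's open promoters with an alternative, 149 kept their call or lack of one, 29 lost and 10 gained a call and 4 changed direction from a call; in 10 more a list without a call changed direction. Of 168 for distal summits 159 kept their side, 1 lost and 8 gained a call. Of 135 for motifs 111 kept their side, 5 lost and 19 gained a call, and of 28 for the log2 ratio 25 kept theirs, 1 lost and 2 gained a call. No paired analysis was possible because there was 1 group. The unknown depth limits every missing peak.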

Other observations

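Chosen only after the results were seen were the gene families, the noncoding classes, the tests of depth and of the list threshold, the CpG and threshold tests on groups of gene lists, the ratio by GC content, the looser search for copies and the matched motif comparison; the tests of CArG boxes, GC content, copies, CpG content at Hox groups 9 to 13 and tRNA genes were set before their results were seen. In the conservative list the chosen gene families followed the contrast between general and specialised functions, without a comparison with CpG-matched genes. All 30 genes of small ribosomal subunit proteins had an open promoter (98.3% ± 2.36 in the replicates, SD, n = 2), as did 41 of 49 of the large subunit, 72 of 78 mitochondrial ribosomal proteins, 63 of 67 core histones, 34 of 39 proteasome subunits and 305 of 394 zinc finger proteins (77.4%), against 51.2% of all genes. Olfactory receptors had 1 open promoter of 1135, with 11 in the replicated list, vomeronasal receptors 1 of 331, keratins 1 of 53, with 10 in the replicated list, and defensins 0 of 64. Collagens had 14 of 44, with 7 and 13 in the lists of replicates 1 and 2. The replicated list opened 33 of them, a share above the 65.7% of all genes there, so their direction turned. Claudins, which form tight junctions, had 5 of 23 (adjusted p = 0.00618, Fisher's exact test), with 6 and 8 in the lists of replicates 1 and 2 and 13 in the replicated list.

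Distal summits were frequent at noncoding genes. Of 7992 distal summits, 198 (2.48%) lay within 1 kb of a tRNA gene, against 0.0269% of random positions, and 122 of 403 tRNA genes (30.3%; 24.2% ± 9.65 in the replicates, SD, n = 2) had such a summit. Long noncoding RNA genes accounted for 930 summits (11.6%, against 1.15%), snRNA and snoRNA genes for 130 (1.63%, against 0.225%), pseudogenes for 184 (2.30%, against 1.01%) and miRNA genes for 69 (0.863%, against 0.161%). Near none of these lay 6583 (82.4%).

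Clusters of tRNA genes were tested as an account of the genes with most distal summits. Of the 10 genes, 3 had a tRNA gene within 50 kb, against 1.64% of other genes: Fcgr3 with 25, Cfap126 with 20 and BC107364 with 15. Fcgr3 and Cfap126 are neighbours, and the 20 tRNA genes near Cfap126 are all among those near Fcgr3, so the genes are not independent and no p-value is given. This was fewer than the 5 set beforehand, so tRNA clusters may account for these genes but not for all 10. Eapp and Tex14 had 7 snRNA or snoRNA genes each within 50 kb and Mreg 4, counted after the result was seen.

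Signal at gut epithelial genes differed between the replicates, and erythroid regions were largely confined to the lists of replicate 2. A deeper or cleaner library in replicate 2 had no separate test, since the values at hand are those that showed these patterns. Sets matched on signal did not share the patterns. The log2 ratio of gut epithelial regions lay at percentile 0 of such sets. The number of erythroid regions outside the IDR list of replicate 1 lay at percentile 99.94, but regions at neighbouring globin genes are not independent. The log2 ratio of the 5 erythroid regions measured in both, 0.13, lay within its range. Depth also stays open for stomach mesenchyme and smooth muscle, whose numbers lay at percentiles 24.34 and 28.01 and whose log2 ratios were not raised. Base composition, measured as GC content of the regions, was excluded as the whole cause of the difference at gut epithelial genes. The ratio changed with GC content at distal regions, from -0.11 in the 909 regions of lowest GC content to 0.22 in 908 of higher content. But smooth muscle exceeded gut epithelium by 0.36 with GC matching and by 0.35 without, the median GC contents being close (0.566 and 0.579). A different mix of wall layers and blood in the 2 dissected pools may contribute. The log2 ratios of stomach mesenchyme (0.05) and smooth muscle (0.16) were not raised towards replicate 2 against matched sets, so these 2 layers lend it no support. The 78 regions with a CArG box and no HNF4, HNF1, GATA or FOX match exceeded the 2245 with the reverse by 0.32 (permutation p = 0.0002). But against sets matched on GC content and signal, all CArG regions lay higher by 0.14 and the others at -0.04. CTCF and E-box regions were also high and AP1 regions low in such sets, so the motif difference is not specific to wall layers, and no difference in biology between the pools was tested because the design names none.

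Many lists had fewer open promoters than other genes. Apart from Hox groups 9 to 13, the groups of lists below were formed once the outcome of each list was known. A group therefore restates the outcomes of its single lists. Singly, 6 lists were each below the range of CpG-matched lists: enteric neural crest, endothelium, mesothelium, germ cells and Hox groups 1 to 5 and 6 to 8. Hox groups 9 to 13 were too, with 0 against 12.3. For these lists CpG content of promoters was not the whole cause. It may account for mature gastric cells and leukocytes, with 3 open promoters against 3.39 (middle 95% 1 to 6). The strict threshold of the conservative list may account for enteric neural crest, endothelium, mesothelium and Hox groups 1 to 5 and 6 to 8 pooled. In the replicated list 73.4% of these genes were open, against 65.7% of others. They were pooled once known to have lost their calls there, which favours this outcome. Endothelium (62.5%) and Hox groups 6 to 8 (50%) were under the share of others, and Hox groups 6 to 8 stayed below CpG-matched genes. The threshold was not the whole cause for 3 lists still called there singly, mature gastric cells, leukocytes and germ cells, nor for Hox groups 9 to 13 (25%, adjusted p = 0.00849, exact test). For intestine, liver, lung, skeletal muscle and heart pooled, 5 of 45 promoters were open, against 12.9 (9 to 17) in CpG-matched lists. In the replicated list 37.8% of these genes were open, against 65.7% of others (p = 0.000201, Fisher's exact test). With both together they lay within the matched range (17, against 20.8, 16 to 26). Only lists already below other genes were pooled, so the pool cannot decide whether CpG content or the threshold was the whole cause. Singly, none of these lists passed against CpG-matched genes, or against other genes in the replicated list, so each list alone stays undecided. No biological explanation was tested, since the design has 1 group.

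The strongest distal peaks lay outside coding sequence, as did most distal summits. Reads from mitochondrial DNA or from other copies of a repeated sequence cannot be told apart from accessible chromatin at these peaks as a set: 3 of the 9 regions had another copy, all of them mitochondrial, against 6 of 200 random distal regions (p = 0.00412, Fisher's exact test), which is more than chance and fewer than the share of at least 50% set beforehand. With a looser search at 80% identity over 50% of the length, 6 of the 9 regions and 15 of the 200 had a copy. Copies outside the assembly were not searched, and no biological explanation was tested.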
